A study of Homo sapiens with 38 samples.

How the data were processed

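Gene expression was measured by single-colour oligonucleotide arrays in total RNA of 19 numbered tumours, each on 2 array types, which makes 38 arrays. The titles number the tumours from 1 to 19 and add the letter A or B. Arrays with the letter A carry 22283 probe sets and arrays with the letter B carry 22645 probe sets, and the types are called array A and array B. Per the labels, every sample is a tumour and no second condition is named, so no groups were compared. The spread over the tumours was described instead, together with the relation of genes to scores of gene lists that had been fixed before the data were examined. The labels do not say whether each tumour came from a separate patient. The p-values of correlations over tumours and of the fits therefore measure the spread between these samples. Those of the list tests measure the spread between random gene lists on the same tumours. That of the pairing check concerns random matchings of arrays.

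The deposited values are linear array intensities, 1 per probe set and array. The scanner software, the background correction and the way probes were combined into probe set values are not given in the sources used here. The 2% trimmed mean of the deposited intensities lay between 1500.35 and 1500.55 on all 19 A arrays, and between 1500.28 and 1500.49 on the 17 B arrays with a value for every probe set. These values lie at a common level, and they were used as deposited. A common trimmed mean leaves the array medians free, and they ranged from 580 to 903.2 on array A. On array B, tumours 5 and 6 lack values for 6262 probe sets each, and genes there were fitted on the remaining tumours. Control probe sets (68 on each array type) were left out of all gene tests. Values below the 10th percentile of all values of an array type (70.1 on array A and 108.3 on array B) were raised to that floor, and log2 was taken afterwards. No detection calls were used, so a level near the floor cannot be told from background, and the number of arrays limits the precision.

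Probe sets were named through GEO's platform annotation with symbols updated by gene identifier from the RefSeq gene table of GRCh38.p14. On array A, 19071 probe sets had 1 symbol, 1043 had several and 2169 were unnamed here. The numbers on array B were 15432, 554 and 6659. A gene took the value of its probe set with the highest mean log2 intensity among those with that single symbol, and different probe sets of a gene were not compared in level. Genes at or above the median of the mean log2 values of all probe sets were kept, which left 7124 genes on array A. A further 3351 genes were measured past that level on array B and not on array A. Y-linked genes were left out of all tables.

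The numbers were checked as a link between the array types on the 168 probe sets that both types carry. After centring, the A and B arrays of the same number correlated with a mean r of 0.799 ± 0.120 (SD, n = 19) across probe sets, which are not independent replicates. All 19 A arrays correlated best with the B array of their own number, and 18 of the 19 B arrays with their own A array. Of 10000 random matchings none reached that mean (highest 0.402, one-sided permutation p = 0.0001, the smallest they can give). The arrays were therefore joined by number. From the 100 of these probe sets that are not controls, the SD between the array types of one tumour was 0.19 on the log2 scale, against 0.46 between tumours on array A and 0.51 on array B. The SD between tumours includes RNA quality, which both arrays of a tumour share (log2 3-prime to 5-prime control ratio of 5.81 and 6.09 for tumour 4). Whether these 100 probe sets stand for other genes was not tested.

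In all, 31 gene lists were fixed before the data were examined, and 29 had at least 4 measured members. The median SD of a list and its mean pairwise Pearson r were set against 10000 random lists of the same size, matched on mean level in 10 classes. The spread test was two-sided and the test of mean r one-sided, with Benjamini-Hochberg adjustment over the 29 lists. A list score is the mean over the measured members of their standardized log2 values. Scores were correlated with two-sided permutation tests (100000 resamples), genes shared by both lists being left out of both. Pearson's r was given again without the 2 tumours farthest from the median of the first score. A score for which 2 clusters improved the Bayesian information criterion by more than 10 was kept out of pooled correlations between scores, which applied to 1 list, and its mean pairwise r and members were tested again within the larger cluster. Each member was also correlated with the score of the other members (two-sided permutation test, 10000 resamples), and these p-values were adjusted over the list alone. For each of 6 main lists, every gene outside the list was fitted against the score with limma (lmFit and eBayes with trend, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Slopes are log2 changes for 1 SD of the score over the tumours. In these fits the members of each other list were also adjusted over that list alone, without adjustment over lists or scores. Some of these passes may therefore arise by chance, and they were not repeated under the alternatives.

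Named genes were chosen by a rule fixed in advance: the 20 genes of largest SD, the 3 members of each main list with the highest and the 1 with the lowest r, the first 5 rising and 3 falling genes of each fit, leading members of the other lists whose mean pairwise r passed, and 6 genes of general interest in this tumour type. Of those 6, TP63 and PTHLH are not analysed here.

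RNA quality was read from the log2 ratio of 3-prime to 5-prime control probe sets of ACTB and GAPDH, averaged over both genes. A ratio of over 4-fold, a limit chosen after seeing the data, set apart 5 tumours (1, 2, 4, 18 and 19), and each leading count of array A was repeated on the other 14. The fits on array B were not repeated under any alternative. The alternatives tried were quantile normalization, division of each array by its median, no level filter, a filter that keeps genes in the top 25% of probe set levels, a pseudocount of 16 in place of the floor, the mean of all probe sets of a gene, omission of probe sets with the suffix _x_at or _s_at, the median as score, ranks, the 3-prime to 5-prime ratio or the fibroblast matrix score as covariate, and leaving out each tumour in turn.

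The fits were tested on simulated data with the real means and SDs and 200 genes tied to the real score among all genes of each fit (7078 to 7109 genes). Over the 6 fits, 17% to 30% of the genes simulated at an r of 0.6 and 77% to 86% of those at 0.8 were recovered, 0 with the wrong sign, and false calls made up 2.52% to 8.94% of calls. For the list tests, 0 of 40 simulated unrelated lists passed in either test. The noise of each simulated gene was independent of that of other genes, whereas real genes vary in groups. These rates of false calls may therefore not hold in the real data, where permuted T/NK cell scores gave up to 112 genes (median 0). The steps were run in R 4.3.3 with limma 3.58.1 and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9.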

Results

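Total RNA of 19 tumours, in a series titled as squamous cell carcinoma of the head and neck, was measured on array A (22283 probe sets) and array B (22645 probe sets). All samples are of 1 kind, and no normal tissue or second condition is named in the labels. The comparisons therefore concern how far genes and gene groups differed between the tumours, which groups rose and fell together, and which genes followed them. Intensities are the authors' scaled values on the log2 scale, with 7124 genes past the level filter on array A. RNA quality differed widely. The ratio of 3-prime to 5-prime control signal, which rises as RNA is degraded, ran from 1.37-fold to 56.1-fold on array A and was over 4-fold in 5 tumours. Tumour 4, which had the highest ratio, resembled the other tumours least. Its highest r across probe sets was 0.769, against 0.844 for the next tumour.

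Genes of the squamous epithelium differed most between tumours. KRT4, a keratin of the suprabasal layers of non-cornifying mucosa, had the largest SD of all genes past the filter, at 10.86 ± 3.97 (SD, n = 19), followed by LTF at 10.06 ± 3.57, KRT13 at 13.34 ± 3.45, KRT19 at 12.17 ± 3.37 and S100A7 at 13.78 ± 3.09. LTF encodes lactoferrin, a protein of glandular secretions and neutrophil granules. The median SD of all genes was 0.55. Of the 20 genes with the largest SD, 8 belong to the keratinocyte differentiation list, where 0.109 would be expected from the list's share of genes (KRT4, KRT13, S100A7, SPRR3, RHCG, CRNN, KRT1 and TGM1). The others also included the cornified envelope genes SPRR2B and SPRR2C, SLURP1, the cancer-testis antigen gene MAGEA6, the collagenase gene MMP1, ALDH3A1, FOSB, the immunoglobulin heavy chain gene IGHM, MLIP and CALB1. KRT4 spanned 10.91 on the log2 scale, KRT19 spanned 10.10 and S100A7 spanned 11.40, with 1, 3 and 1 tumours at the floor. In 11 of the 20 genes at least 1 tumour lay at the floor, and in LTF and SPRR2C it was 4. The ranges and SDs of these genes are lower bounds, so the order of the SDs is not firm. SPRR2B and SPRR2C, and MAGEA6 and its relatives, belong to families of very similar genes, which the probes were not tested to separate. Without the 5 tumours of high ratio the SD was 1.94 for S100A7, 1.93 for SPRR2B, 1.83 for TGM1, 2.34 for SPRR2C and 2.11 for FOSB. The SD of IGHM was 1.55 without probe sets of the suffix _x_at or _s_at.

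**Figure D1:**
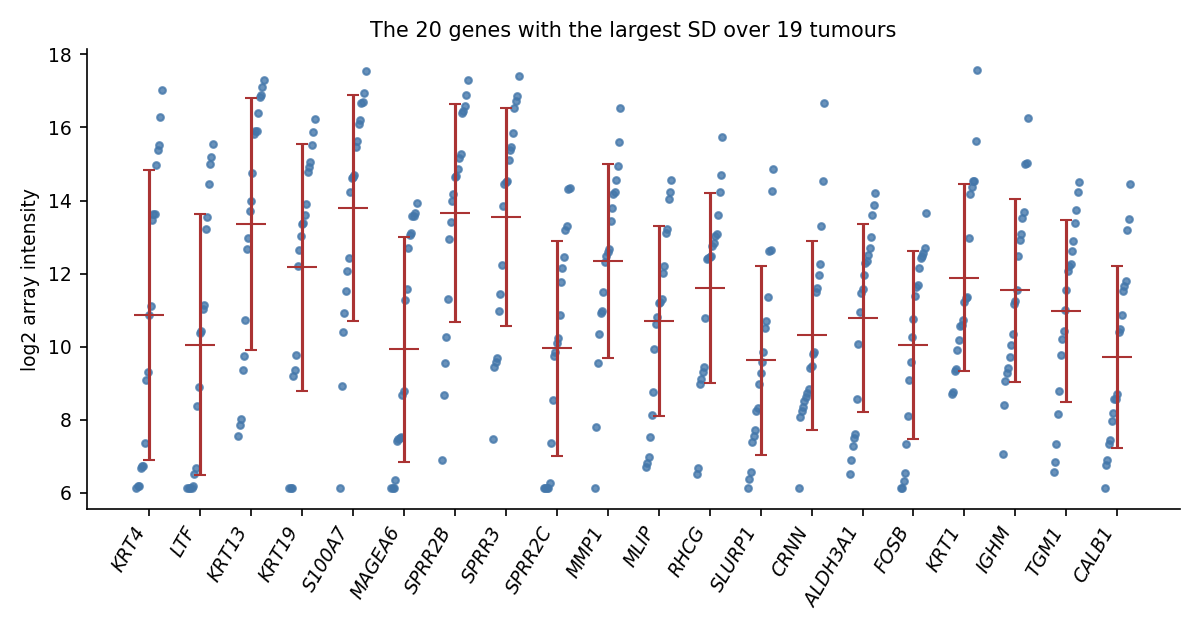
Log2 array intensity (vertical axis) of the 20 genes with the largest SD, 1 point per tumour (19 tumours, ordered by value within a gene), with bars for the mean and 1 SD. KRT4 has the widest SD, 3.97, and the lowest points of several genes lie at the floor.

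Most of the fixed gene lists differed more between tumours than random lists of the same level. The median SD of the keratinocyte differentiation list was 1.91, against 0.54 in random lists (adjusted p = 0.000414). The next widest were the salivary gland list at 1.66, the list of genes at 11q22 at 1.52, which holds the matrix metalloproteinase cluster, and the B and plasma cell list at 1.48. In all 24 of 29 lists passed, although some calls depended on a setting or on single tumours. The ribosomal protein list was the exception in direction, with a median SD of 0.37 against 0.56 in random lists (adjusted p = 0.000414). The lists of endothelium (adjusted p = 0.131), oxidative phosphorylation (0.163), 3q26 (0.131), 7p11 (0.908) and 9p21 (0.908) did not pass. The neutrophil list (adjusted p = 0.0462) did not pass without tumour 4 (0.0890), 14 (0.103) or 19 (0.0552), nor the 11q13 list (0.0308) without tumour 16 (0.0607) or 19 (0.509), nor the 8q24 list (0.0353) without tumour 4 (0.0768), 5 (0.0655) or 11 (0.165). The 3q26 list passed without tumour 4 (adjusted p = 0.0484) and with the 3-prime to 5-prime ratio regressed out (0.0356). With no level filter the mast cell list (8 members instead of 4, adjusted p = 0.0806) and the adipocyte list (11 instead of 4, 0.534) did not pass, while the endothelial list did (17 instead of 6, 0.0354). The neutrophil list also did not pass with each array divided by its median (adjusted p = 0.0515), with the ratio regressed out (0.0529) or without the tumours of high ratio (0.0854), nor the 11q13 list with the mean of probe sets (0.0694) or without those tumours (0.0977). With the mean of probe sets the HPV-associated list, of genes reported as higher in tumours with human papillomavirus, did not pass (adjusted p = 0.624 against 0.0135). The 8q24 list did not pass in 5 settings, which were the stricter filter (0.0702), the mean of probe sets (0.288), no _x_at or _s_at probe sets (0.101), the ratio regressed out (0.112) and no tumours of high ratio (0.0754).

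Mean pairwise r among the members exceeded that of random lists in 26 of the 29 lists. It was 0.691 over the macrophage and myeloid list, led by LAPTM5, TYROBP and FCER1G, and 0.621 over the skeletal muscle list, led by ATP2A1, MB and NEB. The skeletal muscle value leaned on tumour 14, without which it was 0.373 (adjusted p = 0.000435). Mean pairwise r was 0.608 for T and NK cells, 0.583 for proliferation, 0.537 for interferon, 0.531 for B and plasma cells (IGLC1, IGKC, POU2AF1), 0.525 for MHC class II (HLA-DPB1, CD74, HLA-DPA1), 0.50 for fibroblast matrix, 0.495 for mast cells (CPA3, TPSB2, TPSAB1) and 0.493 for keratinocyte differentiation. Lower values were found for immediate early genes (0.451; ZFP36, ATF3, DUSP1), hypoxia and glycolysis (0.369), salivary gland (0.366; STATH, DMBT1, PIP), the EGFR pathway (0.350; HBEGF, DUSP6, FOSL1), oxidative phosphorylation (0.340; COX7B, NDUFS3, COX6C) and ribosomal proteins (0.306; RPS9, RPL22, RPL3). The lists of invasion (0.283; TNC, SNAI2, ITGA5), endothelium (0.278; ENG, VWF, PLVAP), basal keratinocyte adhesion (0.275; CDH3, CLCA2, JUP) and NRF2 targets (0.164; AKR1B10, AKR1C2, SLC7A11) passed at the lowest values of the cell type and pathway lists. The HPV-associated list is counted among the 26 (0.354 over 5 members, adjusted p = 0.00383), and with no level filter the value was 0.165 over 11 members (adjusted p = 0.0176). In the main setting, however, 3 tumours formed a separate cluster of its score. Within the other 16 tumours its mean pairwise r was -0.093 (adjusted p = 0.856), so the pooled call did not hold there. These 16 were set apart by the score itself, which lowers r among its members, so this value does not decide whether they vary together. The largest adjusted p among those that passed was 0.00591. The neutrophil list (0.081, adjusted p = 0.207), the adipocyte list (0.046, adjusted p = 0.403) and the 9p21 list (0.090, adjusted p = 0.238) did not pass. The failure of the neutrophil list depended on the level filter, without which 10 members instead of 5 were measured and mean pairwise r was 0.242 (adjusted p = 0.000954). The endothelial list did not pass with each array divided by its median (0.172, adjusted p = 0.0629). The ribosomal protein value was 0.113 after quantile normalization (adjusted p = 0.00278), and it did not pass over the 7 members left without _x_at and _s_at probe sets (0.117, adjusted p = 0.162). With the stricter filter the value was 0.814 over 4 B and plasma cell genes and 0.842 over 7 MHC class II genes, and with the mean of probe sets it was 0.847 for MHC class II.

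Single members followed the others to different degrees, also in lists whose mean pairwise r passed (permutation test, adjusted over the list alone). All 16 macrophage and all 9 skeletal muscle genes rose with the score of the other members, as did 9 of 12 B and plasma cell, 7 of 9 MHC class II, 3 of 4 mast cell, 11 of 15 immediate early, 20 of 27 oxidative phosphorylation and 14 of 21 ribosomal protein genes. The counts were 5 of 8 for salivary gland, 4 of 6 for endothelium, 11 of 18 for invasion and 7 of 12 for the EGFR pathway. Of 21 basal keratinocyte genes 12 rose, 1 fell and 8 did not pass. Of 20 NRF2 targets 8 rose and 12 did not pass. Of the 5 HPV-associated genes 0 passed in the permutation test within the 16 tumours outside the separate cluster. As these tumours were set apart by the score of the same genes, which lowers r among them, this failure was partly built in. Over all 29 lists 344 members rose, and rho had a permutation p of at least 0.05 for 20 of them. Of the 5 neutrophil and 4 adipocyte genes 0 passed in the permutation test.

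**Figure D2:**
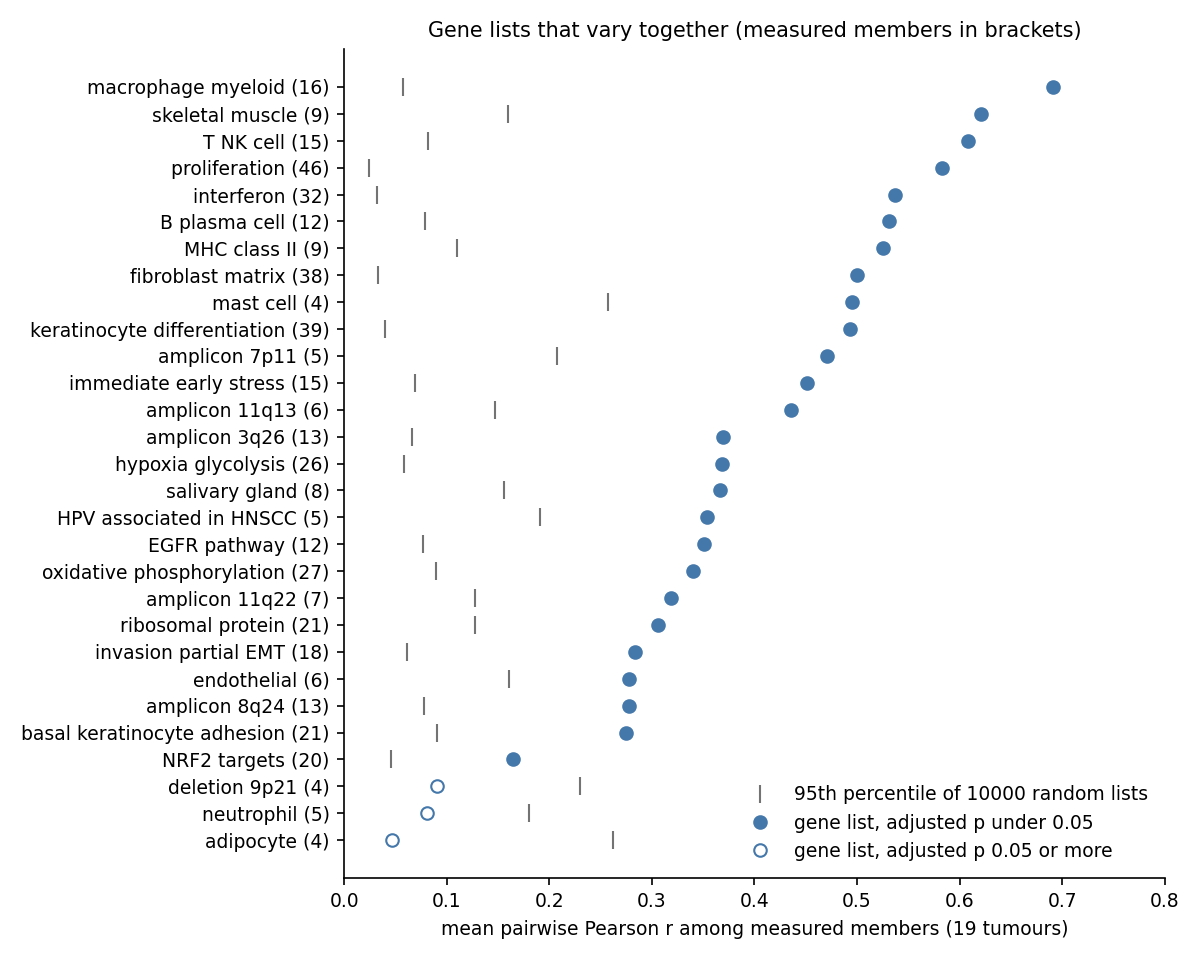
Mean pairwise Pearson r (horizontal axis) among the measured members of 29 gene lists over 19 tumours, with the 95th percentile of 10000 random lists as a grey tick. The 26 filled points passed at an adjusted p under 0.05, and the 3 open points (9p21, neutrophil and adipocyte) did not; the HPV-associated point pools 2 separate clusters and did not pass within the larger one.

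Genes that share a chromosome band often gained in this tumour type formed 5 of the lists whose mean pairwise r passed. Mean pairwise r was 0.471 at 7p11 (CCT6A, CHCHD2, LANCL2), 0.436 at 11q13 (FADD, CTTN, PPFIA1), 0.370 at 3q26 (PDCD10, FXR1, ECT2), 0.319 at 11q22 (MMP10, MMP1, BIRC2) and 0.277 at 8q24 (CYRIB, PTK2, HSF1). All 5 values exceeded the 95th percentile of random lists, which lay between 0.066 and 0.207. The random lists held genes from any chromosome, however, and adjacent genes varied together in general (mean r of 0.143, described below). Random lists of neighbouring genes were not drawn, so these calls do not set the bands apart from other neighbouring genes. Without tumour 19 the value at 11q13 was 0.247 (adjusted p = 0.00915), and without tumour 5 the value at 8q24 was 0.175 (adjusted p = 0.00227). The r with the other 11q13 members was 0.787 for FADD (permutation p = 0.0008; rho = 0.419, permutation p = 0.0759) and 0.731 for PPFIA1 (permutation p = 0.0024; rho = 0.370, permutation p = 0.119). These r were 0.372 and 0.393 without the 2 extreme tumours, and 0.541 and 0.473 without the 5 tumours of high ratio. For BIRC2 at 11q22 r was 0.541 (permutation p = 0.0154) and rho 0.340 (permutation p = 0.154), and r was 0.322 without the 2 extreme tumours. Over 6 members left without _x_at and _s_at probe sets the value at 3q26 was 0.143 (adjusted p = 0.0497). Of the measured members 4 of 5 at 7p11, 5 of 6 at 11q13, 10 of 13 at 3q26, 6 of 7 at 11q22, 6 of 13 at 8q24 and 1 of 4 at 9p21 rose with the others (adjusted over the list alone). Copy number was not measured on these arrays.

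Among the genes of general interest, EGFR, the epidermal growth factor receptor, averaged 13.12 ± 0.81 (SD, n = 19) and spanned 7.60-fold between the lowest and the highest tumour. CCND1, the cyclin D1 gene at 11q13, averaged 11.79 ± 1.00 and spanned 11.8-fold. CDKN2A, which encodes p16, averaged 11.49 ± 1.07 and spanned 14.7-fold. CD274, which encodes PD-L1 and was measured on array B, averaged 11.96 ± 0.98 and spanned 10.7-fold. These SDs were larger than those of 79.9%, 89.6%, 91.7% and 84.4% of the genes of their array.

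Along the keratinocyte differentiation score, 35 of 39 measured members rose with the score of the other members and 4 did not pass (permutation test, adjusted over the list alone). TGM1, the transglutaminase that cross-links the cornified envelope, followed the others most closely (r = 0.931, rho = 0.909), ahead of S100A9 (r = 0.880, rho = 0.865) and the elafin gene PI3 (r = 0.876, rho = 0.860), each with a permutation p of 0.0001 for r and rho, the smallest it can give. Without the 2 extreme tumours these r were 0.912, 0.825 and 0.839. KRT10 did not pass (r = 0.216, rho = 0.191, permutation p = 0.378 and 0.425), with r from 0.057 without tumour 1 to 0.365 without tumour 18. Outside the list, 56 of 7085 genes passed, 51 of them higher and 5 lower with the score (limma, adjusted p under 0.05). SPRR2B rose by 2.71 ± 0.28 (SE, n = 19) for 1 SD of the score, CRCT1, a cysteine-rich gene of the epidermal cluster, by 1.87 ± 0.17, LCN2 by 1.63 ± 0.18, HOPX by 1.45 ± 0.15 and the cholesterol sulfotransferase gene SULT2B1 by 1.09 ± 0.12. The largest limma adjusted p of these was 2.13e-05. NUCKS1 fell by 0.52 ± 0.10, B3GAT3 fell by 0.55 ± 0.12 and RECQL fell by 0.41 ± 0.08. On array B, 32 of 3349 genes were higher and 1 was lower, led by SBSN, SPINK7, VSIG10L, GPR15LG and KRT80, with RHNO1 the lower one. Of the 46 proliferation genes, 15 fell with this score when adjusted over the list alone and 1 (TOP2A) over all genes tested. Of 21 basal keratinocyte genes, 7 rose when adjusted over the list alone and 3 over all genes (DSG3, PERP, JUP). Of 20 NRF2 targets 2 rose when adjusted over the list alone and 1 (AKR1B10) over all genes, and of 5 genes at 7p11 1 fell when adjusted over the list alone and 0 in limma over all genes. Without the 5 tumours of high ratio 26 genes passed, of which 22 were shared, and RECQL (slope -0.31, limma adjusted p = 0.303) and B3GAT3 (slope -0.37, limma adjusted p = 0.424) did not. RECQL also did not pass without tumour 14 (limma adjusted p = 0.0525), nor B3GAT3 without tumour 18 (0.0553) or 19 (0.0531).

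The proliferation list moved as a block. Of 46 measured members 45 rose with the others (adjusted over the list alone), led by the mitotic kinase genes AURKB (r = 0.928, rho = 0.905) and BUB1 (r = 0.916, rho = 0.940) and the cyclin gene CCNA2 (r = 0.910, rho = 0.870), each with permutation p = 0.0001 for r and rho. Without the 2 extreme tumours these r were 0.853, 0.859 and 0.836. KIF20A was lowest, with r = 0.418 and rho = 0.691 (permutation p = 0.0849 and 0.0017), and its r was 0.180 without the 2 extreme tumours. That low r rested on tumour 4, without which it was 0.840, and it was 0.862 without the 5 tumours of high ratio and 0.266 without tumour 14. Outside the list, 39 of 7078 genes passed (30 higher, 9 lower). NEK2, a centrosomal kinase gene, rose by 1.00 ± 0.15 (SE, n = 19) for 1 SD of the score, the kinesin gene KIF18B by 0.67 ± 0.09, the lamin gene LMNB2 by 0.65 ± 0.09, KIF14 by 0.58 ± 0.09 and KIF4A by 0.56 ± 0.09 (limma adjusted p of at most 0.00303). The tight junction gene CLDN4 fell by 1.06 ± 0.19, SASH1 fell by 0.58 ± 0.11 and the muscle gene NEB fell by 1.12 ± 0.23. On array B, 13 of 3351 genes were higher, led by UHRF1, NUF2, BCL2L12, SGO2 and LRR1, and 1 was lower (MYZAP). Adjusted over the list alone, 6 of 9 skeletal muscle genes, 4 of 8 salivary gland genes and 6 of 39 keratinocyte differentiation genes fell with the score. Over all genes tested these counts were 1, 0 and 0. Of 4 mast cell genes 3 fell when adjusted over the list alone and 1 (TPSB2) over all genes, while of 13 genes at 3q26 4 rose when adjusted over the list alone and 2 (ECT2, ACTL6A) over all genes. Of 5 HPV-associated genes 1 (RNASEH2A) rose by both adjustments. When adjusted over the list alone, 2 of 5 neutrophil genes and 1 of 15 immediate early genes fell and 1 of 5 genes at 7p11 rose, but 0 of these in limma over all genes. With each array divided by its median, 155 genes passed (139 higher, 16 lower), while the median slope of all genes moved from 0.00019 to 0.085. The count was 13 without the tumours of high ratio, 14 without tumour 14, 13 without tumour 19, 21 without tumour 5 and 25 without tumour 9. Without tumour 14 NEK2 (limma adjusted p = 0.0638) and NEB (0.394) did not pass, nor did SASH1 (0.0572) and NEB (0.0613) without tumour 19. On the 14 tumours without high ratio CLDN4 (slope -0.81, limma adjusted p = 0.192), SASH1 (slope -0.49, limma adjusted p = 0.152) and NEB (slope -1.28, limma adjusted p = 0.0984) did not pass.

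Genes of T and NK cells were followed by 316 genes, more than any other main list, although with each array divided by its median the interferon (276) and hypoxia (365) counts were higher. Of 15 measured members 14 rose with the others (adjusted over the list alone), led by the T-cell receptor gene TRBC1 (r = 0.95, rho = 0.933), CD2 (r = 0.935, rho = 0.928) and the granzyme gene GZMB (r = 0.934, rho = 0.882), each with permutation p = 0.0001 for r and rho. Without the 2 extreme tumours these r were 0.943, 0.910 and 0.892. IL7R had the lowest value, r = 0.419 and rho = 0.539 (permutation p = 0.0714 and 0.0176). Outside the list, these were 316 of 7109 genes, 239 higher and 77 lower. Among the higher ones were the adenosine deaminase gene ADA2, which rose by 1.67 ± 0.19 (SE, n = 19) for 1 SD of the score, the pan-leukocyte phosphatase gene PTPRC (CD45) by 1.11 ± 0.13, the lymphotoxin gene LTB by 1.09 ± 0.14, CORO1A by 0.94 ± 0.12 and ARHGDIB by 0.85 ± 0.11 (limma adjusted p of at most 0.000139). IL24 fell by 1.78 ± 0.29, the chromatin protein gene HMGA2 fell by 0.97 ± 0.14 and the sphingosine kinase gene SPHK1 fell by 0.68 ± 0.12 (limma adjusted p of at most 0.00179). These 8 genes also passed without the 5 tumours of high ratio, where 191 genes passed and 168 were shared. On array B, 67 of 3351 genes were higher, led by EOMES, a transcription factor of cytotoxic lymphocytes, HCST, RASAL3, NLRC3 and ARHGAP9, and 32 were lower, led by PHLDB2, SH2D5 and AP2A1. The count on array A fell to 183 with each array divided by its median. It was 170 without tumour 5, 202 without tumour 11, 200 without tumour 18 and 507 without tumour 4.

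Genes of 4 other immune lists rose with the T and NK cell score, and those of the neutrophil list did not pass. When adjusted over the list alone, 16 of 16 macrophage and myeloid genes rose, 7 of 9 MHC class II genes, 9 of 12 B and plasma cell genes and 3 of 4 mast cell genes. Over all genes tested these counts were 11, 7, 6 and 2. Of 5 neutrophil genes 0 passed in limma over the list alone or over all genes (median slope 0.09). Genes of hypoxia and glycolysis went the other way, 11 of 26 falling when adjusted over the list alone and 4 over all genes (the glucose transporter gene SLC2A1, ADM, P4HA1 and AK4). Of 46 proliferation genes 6 fell when adjusted over the list alone and 1 (MELK) over all genes. Of 18 invasion genes, 7 fell and 2 rose when adjusted over the list alone, and 1 (SNAI2) fell over all genes tested. Of 21 basal keratinocyte genes, 3 that encode adhesion or basement membrane proteins (ITGA6, ITGB4, LAMB3) were lower over all genes tested and 1 (KRT15) was higher. Adjusted over the list alone 5 were lower and 1 was higher. Of 32 interferon genes 1 was higher, the chemokine gene CXCL10. Some genes outside the immune lists rose too. These were KRT13 and MAL of 39 keratinocyte differentiation genes and PECAM1 of 6 endothelial genes over all genes tested, with counts of 2 and 1 also when adjusted over the list alone. Of 8 salivary gland genes 3 rose when adjusted over the list alone and 0 in limma over all genes. INHBA of 38 fibroblast and matrix genes and FXR1 of 13 genes at 3q26 fell over all genes tested, where the counts adjusted over the list alone were 0 and 2. When adjusted over the list alone 2 of 12 EGFR pathway genes, 2 of 7 genes at 11q22 and 4 of 13 at 8q24 fell, and 0 of these in limma over all genes. The list members named here, and those named in brackets for the keratinocyte, proliferation and hypoxia scores, were chosen after their values were seen.

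Fibroblast and matrix genes rose and fell together, with few genes outside the list. Of 38 measured members 32 rose with the others (adjusted over the list alone), led by the collagen gene COL1A2 (r = 0.948, rho = 0.939), the fibronectin gene FN1 (r = 0.919, rho = 0.925) and COL3A1 (r = 0.899, rho = 0.940), each with permutation p = 0.0001 for r and rho. Without the 2 extreme tumours these r were 0.930, 0.903 and 0.869. ADAM12 did not pass (r = 0.045, rho = 0.082, permutation p = 0.859 and 0.736), with r from -0.101 without tumour 11 to 0.243 without tumour 3. Outside the list 6 of 7086 genes passed, all of them higher. They included the heparan sulfatase gene SULF1, which rose by 0.74 ± 0.11 (SE, n = 19) for 1 SD of the score, the caldesmon gene CALD1 by 0.67 ± 0.10, the procollagen processing gene PCOLCE by 0.71 ± 0.12, OLFML3 by 0.78 ± 0.13 and LRRC17 by 0.85 ± 0.16 (limma adjusted p from 0.00439 to 0.0303). Of 18 invasion genes 1 rose when adjusted over the list alone and 0 in limma over all genes. On array B 0 of 3349 genes passed in limma, with 152 at an unadjusted p under 0.05, fewer than the 167 that chance would give. In limma the count on array A was 0 without tumour 16, with 316 at an unadjusted p under 0.05 against 354 by chance. It was 3 without tumour 3, 10 without tumour 4, 13 without tumour 5, 11 without tumour 14 and 7 without the tumours of high ratio. Without tumour 3 PCOLCE (limma adjusted p = 0.0699) and OLFML3 (0.0714) did not pass, nor did LRRC17 without tumour 5, 10, 11 or 13 (highest limma adjusted p = 0.0862).

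Interferon-induced genes formed another block. Of 32 measured members 29 rose with the others (adjusted over the list alone), led by IFI44 (r = 0.912, rho = 0.937), the oligoadenylate synthetase gene OAS1 (r = 0.891, rho = 0.863) and IFI6 (r = 0.881, rho = 0.826), each with permutation p = 0.0001 for r and at most 0.0002 for rho. Without the 2 extreme tumours these r were 0.910, 0.815 and 0.787. CXCL10 did not pass (r = 0.291, rho = 0.279, permutation p = 0.229 and 0.244), with r from 0.188 without tumour 9 to 0.349 without tumour 2. Outside the list 25 of 7092 genes passed, 20 higher and 5 lower. The cathepsin gene CTSC rose by 0.85 ± 0.10 (SE, n = 19), LY6E by 0.91 ± 0.16, HLA-J by 0.78 ± 0.11, IFITM3 by 0.65 ± 0.11 and HLA-G by 0.62 ± 0.09, while KYAT1 fell by 0.44 ± 0.07, CERK fell by 0.45 ± 0.09 and MIR9-1HG fell by 0.57 ± 0.11 (limma adjusted p from 0.000402 to 0.0303). Whether the probe sets of HLA-G and HLA-J also bind other HLA class I transcripts was not tested. On array B 7 of 3351 genes were higher, led by CMPK2, DDX60L, HELZ2, TMEM65 and GNPTG, in a fit that was not repeated without single tumours or without those of high ratio. Of 15 immediate early genes 7 rose when adjusted over the list alone, as did 2 of 21 basal keratinocyte genes and 1 of 7 genes at 11q22, while 1 of 5 HPV-associated genes fell. In the adipocyte and 3q26 lists 1 gene rose and 1 fell. Over all genes 0 of these passed in limma. The fit on array A rested on single tumours. Tumour 4 had the lowest interferon score (-1.67), and also the highest 3-prime to 5-prime ratio and the highest array median on array A (903.2). In limma 1 gene, CTSC, passed without tumour 4, and 0 passed without the 5 tumours of high ratio, where 306 had an unadjusted p under 0.05, fewer than the 355 that chance would give. The slopes there were 0.61 for CTSC and -0.23 for CERK. Counts were 9, 10, 15, 72 and 9 without tumours 7, 8, 9, 15 and 19. LY6E also did not pass without tumour 8, CERK without tumour 8 or 19 and MIR9-1HG without tumour 7, 8, 9 or 19. With each array divided by its median 276 genes passed (256 higher, 20 lower), while the median slope of all genes moved from -0.03 to 0.07. After quantile normalization 48 passed (35 higher, 13 lower).

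The hypoxia and glycolysis list was less tight. Of 26 measured members 20 rose with the others (adjusted over the list alone), led by the adrenomedullin gene ADM (r = 0.860, rho = 0.754, permutation p = 0.0001 and 0.0003), NDRG1 (r = 0.771, rho = 0.826, permutation p = 0.0002 and 0.0001) and BNIP3 (r = 0.759, rho = 0.686, permutation p = 0.0002 and 0.0016). Without the 2 extreme tumours these r were 0.715, 0.716 and 0.618. MXI1 did not pass (r = 0.143, rho = 0.091, permutation p = 0.556 and 0.705), with r from -0.056 without tumour 8 to 0.266 without tumour 19. Outside the list 30 of 7098 genes passed, 10 higher and 20 lower. Among the higher ones were P3H2, a collagen prolyl hydroxylase gene (1.32 ± 0.27, SE, n = 19, for 1 SD of the score), SCRN1 (0.59 ± 0.13), BMP2 (0.55 ± 0.11), MYO5A (0.53 ± 0.10) and the prion protein gene PRNP (0.49 ± 0.09). The prostaglandin D synthase gene PTGDS fell by 1.30 ± 0.24, FUCA1 fell by 0.66 ± 0.13 and the lymphocyte receptor gene SLAMF1 fell by 0.56 ± 0.10 (limma adjusted p of these 8 from 0.0311 to 0.0370). Adjusted over the list alone, 9 of 12 B and plasma cell genes, 13 of 16 macrophage genes and 10 of 15 T and NK cell genes fell with the score, as did 2 of 6 endothelial genes. In the EGFR pathway list 7 of 12 genes rose, in the basal keratinocyte list 8 of 21 rose and 1 fell, and in the invasion list 6 of 18 rose and 1 fell. Also 4 of 12 genes at 8q24, 2 of 15 immediate early genes, 2 of 5 genes at 7p11, 2 of 7 at 11q22 and 1 of 4 adipocyte genes rose. Over all genes tested 1 of these passed (TRBC1). On array B 2 of 3350 genes were higher (FAM210A and PPP2R2C). The count on array A was not stable. In limma 0 genes passed without tumour 5, 9, 11, 15 or 18, with the 3-prime to 5-prime ratio as a covariate or without the 5 tumours of high ratio, where 1014 had an unadjusted p under 0.05 (355 by chance) and the slopes were 0.58 for MYO5A and -1.41 for PTGDS. It was 179 without tumour 8, 170 without tumour 17, 87 without tumour 4, 86 without tumour 16, 71 without tumour 12, 69 without tumour 2 and 52 without tumour 13. SCRN1 also did not pass without tumour 14. With each array divided by its median 365 genes passed and the split turned to 294 higher and 71 lower, while the median slope of all genes moved from -0.03 to 0.08. After quantile normalization 9 passed (2 higher, 7 lower).

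**Figure D3:**
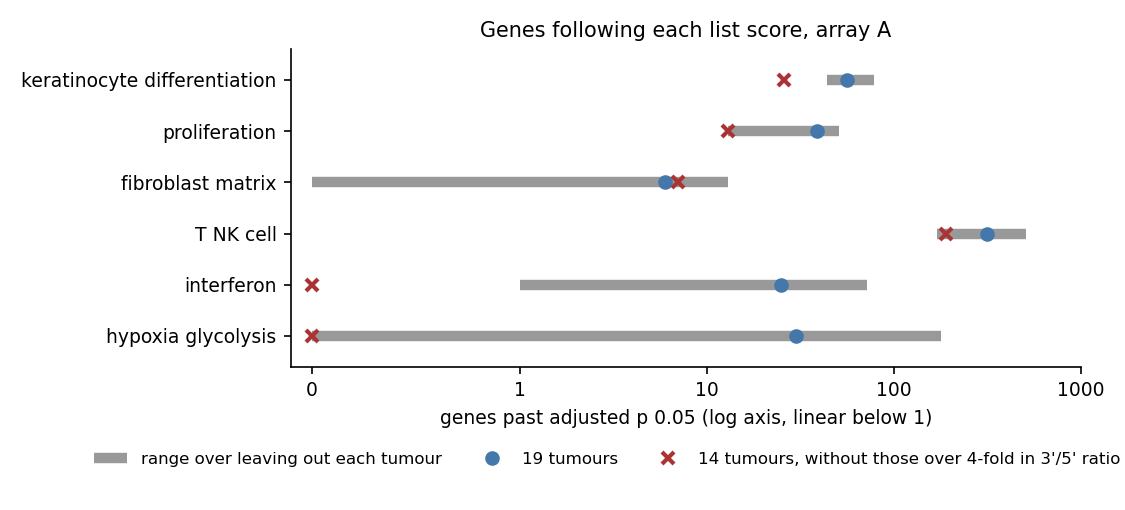
Number of genes on array A past an adjusted p of 0.05 in limma for each of the 6 main scores (horizontal axis, log scale, linear below 1). Blue points are all 19 tumours, grey bars the range when each tumour is left out in turn and red crosses the 14 tumours left without those of high 3-prime to 5-prime ratio. The T/NK cell count of 316 is the highest, and the interferon and hypoxia counts reach 0 on the 14 tumours.

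Between the 6 main scores, 1 of 15 pairs passed. The T/NK cell score ran against the hypoxia and glycolysis score (r = -0.650, permutation p = 0.00252; rho = -0.651, permutation p = 0.00323; n = 19, adjusted p = 0.0378 for r over 15 pairs), and r was -0.564 without the 2 extreme tumours. The r stayed between -0.588 and -0.735 when each tumour was left out, but the adjusted p was over 0.05 for 10 of the 19 (tumours 2, 3, 5, 9, 10, 11, 12, 14, 17 and 18; highest 0.0935), and it was 0.245 with each array divided by its median (r = -0.533). Among the 14 tumours without high ratio r was -0.618 (adjusted p = 0.258). The call also ended with the mean of all probe sets of a gene (r = -0.635, adjusted p = 0.0529) and without probe sets of the suffix _x_at or _s_at (r = -0.612, adjusted p = 0.0781), and over the other settings run the adjusted p was 0.0209 to 0.0484. The keratinocyte differentiation and proliferation scores had r = -0.569 (permutation p = 0.0112) and rho = -0.519 (permutation p = 0.0250), which did not pass over the 15 pairs (adjusted p = 0.0836), and r was -0.420 without the 2 extreme tumours.

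**Figure D4:**
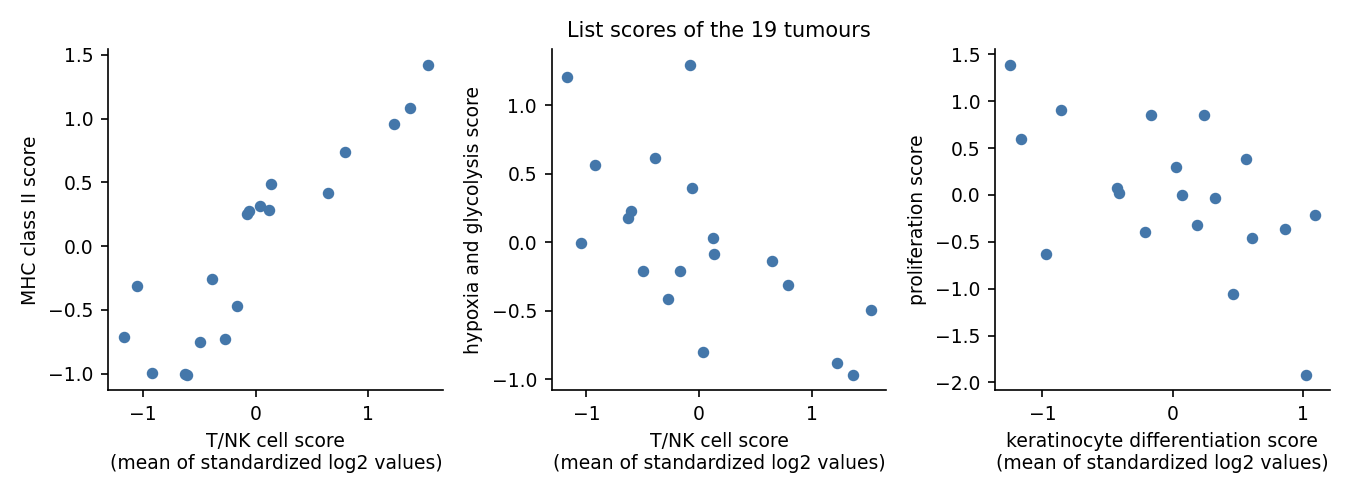
List scores (means of standardized log2 values, without units) of the 19 tumours, 1 point per tumour, for 3 pairs of lists. The T/NK cell score rises with the MHC class II score (r = 0.904) and falls with the hypoxia and glycolysis score (r = -0.650), and the keratinocyte differentiation and proliferation scores (r = -0.569) did not pass the adjusted test.

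Over the 231 pairs of 22 main and secondary lists, 28 passed by Pearson's r, 19 positive and 9 negative. For 22 of the 28 rho passed as well, and for 6 it did not. The T/NK cell score rose with MHC class II (r = 0.904, rho = 0.907, 0.851 without the 2 extreme tumours) and with macrophage and myeloid genes (r = 0.842, rho = 0.847, 0.774 without the 2), each with permutation p = 1e-05 for r and rho, the smallest it can give, and adjusted p = 0.00115 for r. B and plasma cell genes fell as the EGFR pathway rose (r = -0.764, permutation p = 0.00011; rho = -0.802, permutation p = 5e-05; adjusted p = 0.00508; r = -0.702 without the 2). They also fell as hypoxia rose (r = -0.702, permutation p = 0.00072; rho = -0.770, permutation p = 0.00018; adjusted p = 0.0164; r = -0.658 without the 2). The array median had r = 0.620 with the B and plasma cell score and -0.607 with the hypoxia score (adjusted p = 0.0475 and 0.0722, permutation tests). With each array divided by its median the r between these scores was -0.671 (adjusted p = 0.0224). This call ended without tumour 5 (r = -0.629, adjusted p = 0.0620). Keratinocyte differentiation rose with NRF2 targets, genes of the oxidative stress response (r = 0.690, permutation p = 0.00138; rho = 0.677, permutation p = 0.00177; adjusted p = 0.0234; r = 0.607 without the 2), but the call ended with the stricter filter (r = 0.561, adjusted p = 0.0650). Ribosomal protein and oxidative phosphorylation genes rose together (r = 0.854, permutation p = 2e-05; rho = 0.723, permutation p = 0.00091; adjusted p = 0.00154; r = 0.714 without the 2). The proliferation score ran against mast cell genes (r = -0.668, permutation p = 0.00151; rho = -0.730, permutation p = 0.00058; adjusted p = 0.0234; r = -0.774 without the 2), and the adjusted p was 0.0533 without tumour 5 (r = -0.638). It also ran against the neutrophil score (r = -0.695, permutation p = 0.00188; rho = -0.504, permutation p = 0.0299; adjusted p = 0.0271; r = -0.552 without the 2), the salivary gland score (r = -0.629, permutation p = 0.00447; rho = -0.561, permutation p = 0.0135; adjusted p = 0.0397; r = -0.386 without the 2) and the skeletal muscle score (r = -0.639, permutation p = 0.00556; rho = -0.435, permutation p = 0.0640; adjusted p = 0.0459; r = -0.40 without the 2). Without tumour 14 these 3 r were -0.478, -0.410 and -0.337 (adjusted p = 0.192, 0.280 and 0.396). With each array divided by its median they were -0.451, -0.606 and -0.547 (adjusted p = 0.227, 0.0574 and 0.121). The mean of probe sets ended the neutrophil (r = -0.486, adjusted p = 0.158) and skeletal muscle calls (-0.625, 0.0572), and quantile normalization that of skeletal muscle (-0.594, 0.0927). The salivary gland call also ended without tumour 2, 5, 10, 13, 15 or 19, and the skeletal muscle call without tumour 3, 5, 7, 10, 11, 13, 15, 16, 18 or 19. The rho of these 3 relations did not pass over the 231 pairs (adjusted p = 0.117, 0.0840 and 0.195). Of the 5 neutrophil members 0 passed a permutation test against the score of the others. The rho of the mast cell with the endothelial score (adjusted p = 0.0956), of hypoxia with macrophages (0.0594) and of basal keratinocytes with the EGFR pathway (0.0837) did not pass either. Of the 28 calls 16 were kept with each array divided by its median, and 10 whichever tumour was left out. Without tumour 5 only 12 of the 231 pairs passed. With the 3-prime to 5-prime ratio as covariate 30 passed. Among the 14 tumours without high ratio 4 passed, although all 28 relations kept their sign there, with a median absolute r of 0.693 against 0.684 on all 19. The largest loss was between the basal keratinocyte and EGFR pathway scores, with r = 0.348 on the 14 tumours against 0.628.

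The 3-prime to 5-prime ratio and the array median were set against each main score, and 0 of 12 relations passed a permutation test (smallest adjusted p = 0.0722 for Pearson's r). The closest was between the array median and the hypoxia score (r = -0.607, permutation p = 0.00602; rho = -0.661, permutation p = 0.00254; r = -0.744 without the 2 extreme tumours), and its rho passed over the 12 relations (adjusted p = 0.0305). The interferon score had r = -0.546 with the array median (permutation p = 0.0153; rho = -0.468, permutation p = 0.0444; adjusted p = 0.0919 for r), and r was -0.216 without the 2 extreme tumours. Among 32 relations with the secondary scores, 3 passed, all with the array median. These were the mast cell score (r = 0.682, permutation p = 0.00076; rho = 0.572, permutation p = 0.0114; adjusted p = 0.0208; r = 0.607 without the 2), the endothelial score (r = 0.659, permutation p = 0.0013; rho = 0.609, permutation p = 0.00694; adjusted p = 0.0208; r = 0.624 without the 2) and the B and plasma cell score (r = 0.620, permutation p = 0.00445; rho = 0.507, permutation p = 0.0279; adjusted p = 0.0475; r = 0.604 without the 2). Their rho values did not pass over the 32 relations. The strongest relations with the 3-prime to 5-prime ratio were negative and did not pass. They were those of the immediate early score (r = -0.594, permutation test, adjusted p = 0.0551) and of 3 others at adjusted p = 0.096. These were the EGFR pathway (r = -0.520), invasion (r = -0.490) and basal keratinocyte scores (r = -0.483). Without the 5 tumours of high ratio the 4 values of r were 0.034, -0.170, -0.074 and 0.317.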

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

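The omission of the 5 tumours of high 3-prime to 5-prime ratio, ranks without moderation, single tumours left out of the list tests and of the lowest list members, the ratio regressed out of the lists or used as a covariate over all pairs, the other settings over all pairs, 1 list within the larger cluster of its score, and rank correlations with array quality were chosen after seeing the data. No paired analysis was possible because all samples are of 1 kind and the shared numbers only join the array types of one tumour. The pairing check gave a mean r of 0.843 without control probe sets. The counts of lists whose spread or mean r passed stayed within 1.5 times of 24 and 26 in every setting run, and of 1590 single list values 1563 kept their side of the threshold. Of 1400 slopes of named genes under the alternatives 0 changed sign and 180 lost their call. These genes were picked by their fit on the same tumours, and nearly all alternatives use all tumours or all but 1. A change of sign was therefore unlikely from the start. Where a cause is not named below, the cause was not tested.

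The counts of genes following the keratinocyte, proliferation, fibroblast, T/NK cell, interferon and hypoxia scores were 56, 39, 6, 316, 25 and 30. Division of each array by its median gave 155 (proliferation), 11 (fibroblast), 183 (T/NK cell), 276 (interferon) and 365 (hypoxia). Quantile normalization gave 48 (interferon) and 9 (hypoxia). The stricter filter gave 12 (proliferation), 179 (T/NK cell) and 49 (hypoxia), and no filter 1 (hypoxia). The counts of the stricter filter come with fewer genes tested (3852 in all). The mean of probe sets gave 69 and the median score 70 (hypoxia). Omission of _x_at and _s_at probe sets, which leaves 4187 genes, gave 31, 22, 12, 188 and 6 for the first 5 scores. The 3-prime to 5-prime ratio as covariate gave 12 (fibroblast), 10 (interferon) and 0 (hypoxia), and the fibroblast score as covariate 13 (interferon) and 91 (hypoxia). Ranks gave 1, 0, 0, 0, 0 and 0, because normal scores have 1 variance for all genes, which limma's moderation then misreads. Without moderation ranks gave 68, 28, 2, 272, 16 and 27. Without the tumours of high ratio, and so with 14 tumours, the counts were 26, 13, 7, 191, 0 and 0. Leaving out each tumour in turn gave 44 to 78, 13 to 51, 0 to 13, 170 to 507, 1 to 72 and 0 to 179.

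Of the 15 main pairs 1 passed. The number was 0 with arrays divided by their median, with the mean of probe sets, without _x_at and _s_at probe sets and without the tumours of high ratio, 2 with the fibroblast score as covariate (over fewer pairs), and 0 to 2 when each tumour was left out. Of all 231 pairs 28 passed, 12 to 31 when each tumour was left out, 17 with the stricter filter (120 pairs), 17 without _x_at and _s_at probe sets (153 pairs), 30 with the ratio as covariate and 4 on the 14 tumours without high ratio, where there are fewer samples and the 28 relations had a median absolute r of 0.693 instead of 0.684. For array quality 1 relation instead of 0 passed with ranks. Values at the floor hide differences between dim genes.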

Other observations

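Chosen after the result was seen were the tests of the list in separate clusters without single members and within 1 cluster, the permuted scores, the basal keratinocyte score held constant, the reading of the planned median division and ratio covariate as tests of an explanation, and the windows of adjacent genes.

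The list of genes reported as higher in human papillomavirus-associated tumours had 5 measured members, and its score fell into separate clusters. A model of 2 clusters improved the Bayesian information criterion by 16.3, and 3 of the 19 tumours lay between 1.17 and 1.62 while the other 16 lay between -0.76 and 0.15. STAG3, a meiotic cohesin gene, also had 3 tumours between 11.86 and 12.52 and the other 16 between 7.38 and 10.13 on the log2 scale. CDKN2A ran from 9.40 to 13.28 and the transcription factor gene MYB from 7.16 to 13.50, with their largest gaps elsewhere, and RNASEH2A and RFC5 did not split in this way either. Within the 16 tumours, which were set apart by the score itself, mean pairwise r was -0.093 (adjusted p = 0.856) and 0 of the 5 members passed against the others in a permutation test (adjusted over the list alone). The 3 tumours with the highest score were also the 3 highest for STAG3. Of these tumours 2 were among the 3 highest for CDKN2A, for RFC5 and for MYB, and 1 for RNASEH2A. The 3 tumours stayed above the gap of the score without any 1 member. The gain of 2 clusters fell to 9.35 without STAG3 and to 4.57 without RFC5, however, below the limit of 10. Virus status is not given in the sources used here, and no test of it was made.

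Chance pairing of score and tumours was examined with 100 permuted scores for each main list. With the real score counted in, 1 arrangement, the real one, gave as many genes for the keratinocyte (56, highest other 1), proliferation (39, highest other 2), fibroblast (6, highest other 1), T/NK cell (316, highest other 112) and interferon scores (25, highest other 0). For the hypoxia score it was 2 arrangements (30, highest other 32). So many genes were thus rare under chance pairing, in under 5% of the arrangements for each score, without adjustment over the 6 scores. For the hypoxia score a permuted score gave more genes than the real one, so chance is not excluded there. The fibroblast and hypoxia counts also fell to 0 without single tumours.

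The opposite course of the T/NK cell and hypoxia scores might come from how the arrays were scaled, from RNA quality or from the share of keratinocytes. With each array divided by its median r was -0.533 (permutation p = 0.0188), with the 3-prime to 5-prime ratio held constant it was -0.649 (permutation p = 0.00243) and with the basal keratinocyte score held constant it was -0.541 (permutation p = 0.0172). The value for RNA quality, as read from the ratio, argues against it as the whole cause. The value for scaling argues only against a shift that this division undoes as the whole cause. The array median had r = 0.413 with the T/NK cell score and -0.607 with the hypoxia score, and it was not held constant. The basal keratinocyte score stands only loosely for the share of keratinocytes, since the mean pairwise r of its list was 0.275. It also rose with the hypoxia score itself (r = 0.679), so holding it constant cannot decide on that share. Division by the median weakened r from -0.650 and ended its call over 15 pairs (adjusted p = 0.245), so a part played by scaling stays open. No biological explanation was tested, since the labels name no groups.

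Genes that are neighbours on a chromosome varied together. Mean r was 0.143 for 7098 adjacent pairs, 0.120 for genes 2 apart, 0.083 for genes 10 apart and 0.053 for genes 50 apart, against 0.013 at most for adjacent pairs in 100 random gene orders. Windows of 15 genes exceeded the highest random value of 0.290 at 18 separate places on 11 chromosomes. Of these 18 windows 9 were below 0.290 with the 3 leading components removed, 6 with the 3-prime to 5-prime ratio regressed out and 6 without the tumours of high ratio, and 12 were in at least 1 of these 3 settings. Against the highest random values of these settings (0.243, 0.252 and 0.266) the counts were 4, 2 and 5. The first was the epidermal cluster from S100A11 to S100A6 (0.594) and the second ran from YEATS2 to MAGEF1 on chromosome 3 (0.439). These genes were named after their values were seen.

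Related genes could produce this, as could RNA quality or broad components such as cell composition. Adjacent pairs kept a mean r of 0.135 without pairs that share the first 3 letters of their symbols, of 0.153 with the 3-prime to 5-prime ratio regressed out and of 0.154 with the 3 leading components removed, each far above the random orders. These values argue against pairs of like symbols, RNA quality as read from the ratio and the 3 leading components as the whole cause. Cell composition outside these components and related genes with unlike symbols were not tested. Single windows differed, however. The window from S100A11 to S100A6 fell to 0.248 with the components removed, against a highest random value of 0.243, while that from YEATS2 to MAGEF1 stayed at 0.446. Regional base composition was not tested, and no biological explanation was tested, so differences in gene copy number remain a hypothesis only.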
